A study of Mus musculus with 10 samples.

How the data were processed

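The material was tracheal subepithelial mesenchyme of 10 male FVB/NJ mice, 5 exposed to chlorine 4 days earlier and 5 unexposed, with 1 array per mouse. Per the labels' protocols, frozen sections were stained with hematoxylin and eosin, tissue was collected by laser-capture microdissection and combined over sections of a mouse, RNA was purified with the PicoPure kit, and labelled cRNA was made with the Affymetrix WT Plus kit. Regions were chosen by their place under the epithelium on stained sections, per the labels. The mice are separate animals, so that the spread between arrays holds biological as well as technical variation. The deposited values are log2 intensities summarised per probe set by robust multi-array averaging (RMA) in Partek 6.6, per the submitters' processing notes. The log base was taken from the range of the values and from RMA; the RMA settings and any filter on probe sets are not given in the sources used here. Values were used as deposited, with no further normalization in the main test. The table held 41345 probe sets, and all of its sample columns matched a mouse by name. Scanner files were not used here, so that no gene could be called above or below background and low values have no detection limit. For arrays, precision is limited by their number.

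Probe sets were named through the platform annotation given with the data. Of the 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 were not listed, which leaves them unnamed here. Symbols were compared through gene identifiers with the RefSeq gene table of assembly GRCm38.p6, in which 23328 were found, and 0 symbols changed. The genome build of the array annotation is not given in the sources used here, so no coordinates are printed. Each gene's value was the mean log2 value of its probe sets with that 1 symbol, which gave 22180 genes, of which 1082 had more than 1 probe set. Among 136 called genes with several probe sets, the probe sets of 3 differed in the sign of the change.

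The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, no covariate, no block), and p was adjusted by the Benjamini-Hochberg method over all genes. A gene was called at an adjusted p under 0.05. A set of 51 gene lists with 927 entries, 901 of them distinct, was written before the data were examined, as were the tests, the rule for named genes and the alternatives, apart from those said to be chosen after the data were seen. Single-symbol probe sets measured 852 of the entries; the other 75, among them Krt5, Per2 and most globin genes, were not analysed here. The 50 lists with at least 5 measured genes were compared with the other genes by limma's camera with a correlation between genes preset at 0.01, again with the correlation estimated from the data, and by fry, which asks whether a list's genes move in 1 direction without comparing them with other genes. The mean of each list per mouse was compared by a two-sided exact permutation test over all relabellings of the 10 mice, which cannot give a p under 0.00794. List tests were adjusted over the 50 lists. For each list, single genes were also adjusted over the list alone. Lists share members, and a shared gene counts under each.

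Genes were named by 3 rules. The 12 largest rises and 12 largest falls were taken among called genes whose groups did not overlap, leaving out gene models, non-coding names and antigen receptor segments. Each list gave up to 2 rises and 2 falls with the largest changes among its called genes. Where none was called, the rule gave up to 2 genes with the smallest p. These were Ptch1 (-0.34) and Shh (0.26) for hedgehog, Tpsab1 (0.66) and Mcpt4 (-0.73) for mast cells, and Ccr3 (-0.29) and Siglecf (0.24) for eosinophils. They were also Car3 (-0.64) and Retn (-0.52) for adipocytes, Slc4a1 (0.12) for the erythroid list, and Uqcrfs1 (0.25) and Atp5pb (0.18) for oxidative phosphorylation. None passed (adjusted p 0.07 to 0.732), and the counts over named genes below leave them out. Col1a1, Col3a1, Fn1, Acta2, Tgfb1, Epcam, Mki67 and Ptprc were named whatever their values. Other genes were named after their values were seen, as the text says at each.

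Alternatives were another quantile normalization, centring on array medians, filters on dim genes, the brightest probe set per gene, each probe set by itself, eBayes with trend and robust settings, array weights, the mouse number as a block, each mouse left out in turn, an adjusted p under 0.01, a fold of at least 2, and a test against a 1.2-fold change. Lists were also tested without the genes that several lists share. Chosen after the data were seen were the fit without exposed mice 1 and 3, the pan-epithelial mean without each mouse and the fit with a pan-epithelial mean (Epcam, Cdh1, Krt8, Krt18, Krt19 and Cldn7) as a covariate. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and figures with matplotlib 3.10.9.

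The comparison of exposed with unexposed mice was tested on simulated data, in 5 runs over 22180 genes with the real means and spreads. Of changed genes, 34.0% were called at a log2 change of 0.5, 77.6% at 1, 100% at 2 and 98.8% at 3, and 4.3% of calls were of unchanged genes. Genes were drawn independently of each other, with 250 changed genes of each size over the 5 runs. Fewer genes were thus changed than were called on the real arrays, where genes also move together. The simulated shares therefore need not hold there. A list raised in the simulation was called in 5 of 5 runs, with 1 call of an unchanged list. That count does not give the rate of false list calls on the real arrays. There, splits of the mice other than the real one called from 0 to 31 lists with the preset correlation between genes. That range is not a rate of false calls either, since uneven splits keep part of the difference between exposed and unexposed mice.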

Results

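Gene expression was measured in tissue dissected from beneath the tracheal epithelium of 5 mice killed 4 days after they had breathed chlorine gas and of 5 mice that had not. All were 9-week-old males of the inbred strain FVB/NJ, and the exposed mice had spent 1 hr in air holding 235 ppm of chlorine. The series title concerns fibrotic lesions developing in the trachea, and the comparison asks which transcripts differed in the mesenchyme, the connective tissue layer, at that time. Chosen areas were lifted from stained frozen sections by laser-capture microdissection, the material of each mouse was pooled, and 1 array was hybridised per mouse, so that the number of arrays limits the precision of every value. Each array held 41345 probe sets, with median log2 values between 5.10 and 5.18, and 22180 genes were tested. Across genes, which are not independent replicates, Pearson's r between arrays was 0.982 to 0.986 within the unexposed group, 0.947 to 0.983 within the exposed group and 0.928 to 0.972 between the groups. The leading principal component carried 46.3% of the variance and placed all 5 exposed arrays below the unexposed ones, with exposed mouse 1 nearest to them at -2.81 and exposed mouse 3 farthest at -55.9.

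At 4 days after chlorine, the captured tissue held more transcript of genes listed for basal and esophageal epithelium, of genes of cell division, of collagens and other matrix, of macrophages and of chemokines. It held less of genes of ciliated and secretory airway cells, of cartilage and of the circadian clock. These lists were called with a preset correlation between genes, and with an estimated one the clock list kept its call (adjusted p = 0.0399) while the others lost theirs (adjusted p = 0.125 to 0.535). By exact permutation of the mouse means, the ciliated and cartilage lists did not pass (adjusted p = 0.0547 and 0.0768). Of the 22180 genes, 1298 were higher and 1102 lower in exposed mice at an adjusted p under 0.05, and 411 and 349 of these differed at least 2-fold. Without unexposed mouse 1 or unexposed mouse 4, 725 and 723 genes were lower. The groups did not overlap for 1038 of the genes called higher and 876 of those called lower. Among all genes tested the groups did not overlap for 11%, against 0.794% given by chance. The largest rise was that of Sprr1a, a precursor of the cornified envelope of squamous epithelium, from a mean log2 value of 4.28 ± 0.25 (SD, n = 5) to 10.8 ± 0.46 (SD, n = 5), a 92.2-fold difference (log2 change 6.53, SE 0.21, adjusted p = 4.26e-08). Among the 12 largest rises were also the keratins Krt6a (39.8-fold), Krt14 (19.9-fold) and Krt16 (13.4-fold), the differentiation-associated peptide Krtdap (18.2-fold) and the desmosomal cadherin Dsg3 (15.6-fold). Psca, which encodes a surface protein anchored by a lipid tail, rose 45.1-fold, Dynap 39.6-fold and the protease inhibitor Serpinb2 26.9-fold. The platelet chemokine Ppbp rose 33.2-fold, the monocyte-attracting chemokine Ccl8 15.8-fold and Timp1, an inhibitor of matrix metalloproteinases, 12.8-fold. Unexposed means lay below the array medians for Dynap (3.59), Krt16 (3.99), Dsg3 (4.01), Krtdap (4.25), Sprr1a (4.28), Psca (4.61), Ppbp (4.65) and Krt6a (4.92). With no detection limit at hand, the size of these folds is uncertain. The largest fall was that of Sftpa1, which encodes a surfactant-associated collectin, from 10.7 ± 0.28 (SD, n = 5) to 5.75 ± 1.21 (SD, n = 5), so that it was 30.6-fold higher in unexposed mice (log2 change -4.94, SE 0.47, adjusted p = 0.000106). Among the other largest falls, Cxcl15 was 18.6-fold higher in unexposed mice, Sec14l3 16.4-fold, the cytochrome P450 gene Cyp2a5 14.4-fold, the cadherin-related genes Cdhr3 and Cdhr4 13.7-fold and 12.2-fold. The apical cilium gene Sntn was 12.5-fold higher in unexposed mice, Tmem212 11.8-fold, the secreted protein Bpifb1 10.8-fold, A2ml1 10.1-fold and the mucin Muc16 9.47-fold. Retnla, a secreted protein induced by type 2 cytokines in macrophages and airway cells, was 10.9-fold higher in unexposed mice. Krt6a and Krt6b, Cyp2a5 and Cyp2a4, Chil3 and Chil4, and Ccl8 and Ccl12 are close paralogs that array probes may not fully separate, so their single values are uncertain. Where leaving out 1 mouse ended a call, the mouse is named with the range of adjusted p over the 10 such fits. Tmem212 lost its call without exposed mouse 4 or unexposed mouse 1 or 4 (adjusted p 0.00339 to 0.0541, highest without unexposed mouse 1). The log2 change of Krtdap became 5.08 without exposed mouse 3, and those of Psca and Serpinb2 6.16 and 5.43 without unexposed mouse 2. Without exposed mouse 3 the changes of Cxcl15, Cyp2a5, Bpifb1 and A2ml1 became -3.62, -3.06, -2.75 and -2.49. Without exposed mouse 1 those of Cxcl15, Cdhr3, Sntn, Tmem212 and Bpifb1 became -4.80, -4.41, -4.28, -4.23 and -4.08, and without exposed mouse 5 those of Sntn and Tmem212 became -3.04 and -2.92.

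**Figure D1:**
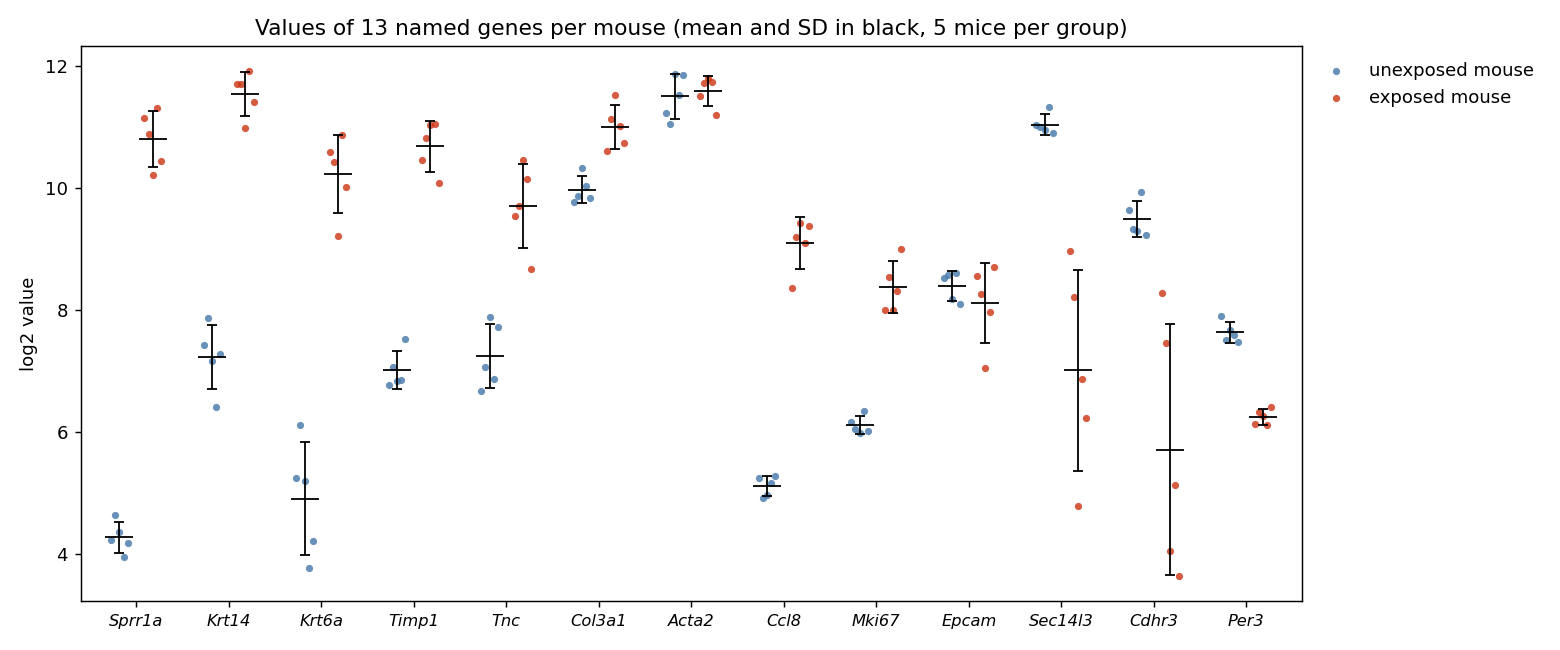
Log2 values of 13 named genes in each mouse, with unexposed mice in blue and exposed mice in red, 5 per group, and the group mean and SD in black. Sprr1a lay between 10.2 and 11.3 in every exposed mouse and at or below 4.64 in every unexposed mouse, while Cdhr3 ranged from 3.65 to 8.28 among exposed mice and Acta2 overlapped between the groups.

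Epithelial transcripts were abundant in the dissected tissue of both groups, and their makeup differed. Basal cell genes were higher and ciliated cell genes lower in exposed mice, while the mean of 6 genes shared by epithelial cells in general differed by -0.022 (exact permutation p = 0.937, n = 5 per group). That difference was 0.143 without exposed mouse 3, also turned above 0 without unexposed mouse 1, 2 or 4, and ranged from -0.104 to 0.143 over the 10 mice left out, a check added after the data were seen. Those 6 genes (Epcam, Cdh1, Krt8, Krt18, Krt19 and Cldn7) were chosen after the data were seen. Their mean joins opposite changes, so it does not show that the epithelial share was equal. With 1 mouse left out, Krt8 changed by 0.278 to 0.414 (limma adjusted p 0.0661 to 0.207) and Epcam by -0.434 to -0.018. Epcam itself changed by -0.28 (SE 0.27, adjusted p = 0.592), or by -0.018 without exposed mouse 3, and in unexposed mice the secretory cell gene Scgb1a1 stood at a mean log2 value of 12.9. Of the 17 basal epithelium genes measured, 7 rose and 0 fell (9 and 0 adjusted over the list alone), with a mean log2 change of 1.15 for the list (adjusted p = 1.25e-06 against other genes, adjusted p = 0.312 with an estimated correlation). Krt6a and Krt14 led it, with log2 changes of 5.32 and 4.31. Of 22 ciliated epithelium genes, 8 fell and 0 rose (17 and 1 adjusted over the list alone), and the list mean changed by -1.57 (adjusted p = 2.70e-08, adjusted p = 0.397 with an estimated correlation). Cdhr3 and Sntn showed its largest falls, -3.77 and -3.64. Of 27 luminal and secretory genes, 4 fell, 1 rose and 22 did not pass (7 and 3 adjusted over the list alone), with a mean change of -1.07 (adjusted p = 0.000777, adjusted p = 0.535 with an estimated correlation). The falls were those of Sec14l3 (-4.03), Bpifb1 (-3.44) and the transcription factors Foxa2 (-0.57) and Spdef (-0.56), and the rise that of Krt7 (0.47); Scgb1a1 changed by -2.15 (SE 0.85, adjusted p = 0.140). Of 10 submucosal gland genes, Pigr, the carrier of secreted immunoglobulin (-2.81), and Prom1 (-2.11) fell, none rose and 8 did not pass (2 and 0 adjusted over the list alone), and the list did not pass against other genes (mean -0.61, adjusted p = 0.311). By exact permutation of the mouse means it did (adjusted p = 0.0317), with 5.08 to 6.39 in exposed and 6.34 to 6.68 in unexposed mice. Of 8 esophageal epithelium genes, 4 rose, Sprr1a (6.53), Krt13 (2.96), Sprr3 (2.50) and Krt78 (0.66), and 0 fell (5 and 0 adjusted over the list alone), with a mean of 1.84 (adjusted p = 0.000113, adjusted p = 0.266 with an estimated correlation); Krt4 changed by 1.25 (adjusted p = 0.449). Foxa2, Spdef, Sprr3, Krt78, Krt4 and Scgb1a1 were named after their values were seen.

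The exposed mice differed among themselves in these epithelial lists more than the unexposed mice did. The ciliated mean was 7.51 in exposed mouse 1 and 7.003 in exposed mouse 2, against 5.75, 4.90 and 4.85 in exposed mice 4, 3 and 5 and 7.39 to 7.86 in unexposed mice. Exposed mouse 3 held the lowest basal mean of its group (7.31, with 8.42 to 8.57 in the others), and the lowest luminal and secretory mean (6.26, with 8.34 to 9.23). It also held the lowest pan-epithelial mean (8.27, with 8.93 to 9.26) and the highest mean of fibrillar matrix genes (9.82, with 8.95 to 9.41). Exposed mice 1 and 3 were left out for their epithelial means, after the data were seen, so the counts without them are not independent of that choice. Without them, 11 basal genes rose and 0 fell, 16 ciliated genes fell and 0 rose, and 12 luminal and secretory genes fell and 2 rose. In that fit Scgb1a1 (-1.40, adjusted p = 0.00416, with 0.00416 to 0.229 over its alternatives) and Krt4 (2.12, adjusted p = 0.0079, with 0.00311 to 0.636) passed the threshold. Both also passed without exposed mouse 3 alone (-1.17, adjusted p = 0.0161, and 2.24, adjusted p = 0.00311). With the pan-epithelial mean of each mouse as a covariate, also chosen after the data were seen, 14 luminal and secretory genes fell and 3 rose, 10 basal genes rose and 0 fell, and 10 ciliated genes fell and 1 rose. In that fit Scgb1a1 passed (adjusted p = 0.0208). Krt7 lost its call without exposed mouse 4 or unexposed mouse 2 (adjusted p 0.0115 to 0.0506, highest without unexposed mouse 2). Prom1 lost its call without unexposed mouse 1 or 4 (adjusted p 0.00628 to 0.0555, highest without unexposed mouse 4). Krt13 lost its call in 8 of the 10 fits, all but those without exposed mouse 3 or unexposed mouse 2 (adjusted p 0.000902 to 0.102, highest without exposed mouse 5). Without exposed mouse 3 the luminal and secretory mean change was -0.57, and Krt13 and Pigr changed by 3.81 and -2.13.

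**Figure D2:**
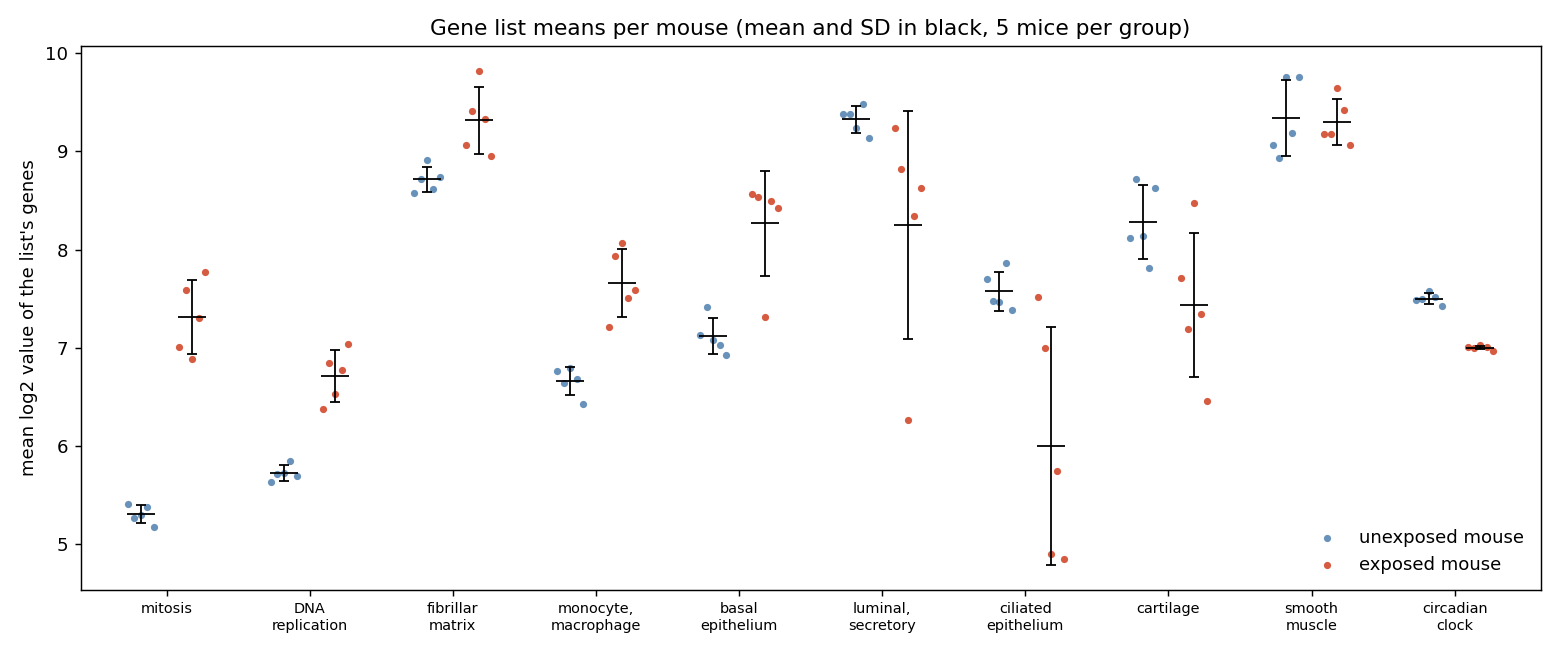
Mean log2 value of the measured genes of 10 gene lists in each mouse, with unexposed mice in blue and exposed mice in red, 5 per group, and the group mean and SD in black. Mitosis means lay between 6.88 and 7.78 in exposed mice and between 5.18 and 5.41 in unexposed mice, ciliated means ranged from 4.85 to 7.51 in exposed mice, and smooth muscle means overlapped.

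Genes of cell division were higher in every exposed mouse than in every unexposed mouse when averaged over each list. All 28 measured mitosis genes rose (28 adjusted over the list alone), by 2.00 log2 units on average, or 4.01-fold (adjusted p = 9.11e-42, adjusted p = 0.125 with an estimated correlation). Ccna2, a cyclin, rose 6.72-fold (log2 change 2.75, SE 0.19, adjusted p = 2.13e-05), the ubiquitin-conjugating enzyme Ube2c 6.27-fold, and Mki67, the proliferation antigen, 4.80-fold from 6.12 ± 0.15 to 8.38 ± 0.42 (SD, n = 5 each). Of 23 DNA replication genes, 20 rose and 0 fell (23 and 0 adjusted over the list alone), with a mean of 0.99 (adjusted p = 3.45e-21, adjusted p = 0.174 with an estimated correlation). Rrm2, a subunit of the enzyme that makes deoxynucleotides, rose 4.75-fold and the helicase subunit Mcm5 2.80-fold. Of 13 p53 targets, 4 rose and 0 fell (5 and 0 adjusted over the list alone), namely the cell cycle inhibitor Cdkn1a (1.03), Eda2r (0.85), Phlda3 (0.44) and Tnfrsf10b (0.32), the last pair named after their values were seen. The p53 list did not pass against other genes (mean 0.19, adjusted p = 0.0603), although it passed without exposed mouse 2 (adjusted p = 0.0492) or unexposed mouse 1 (adjusted p = 0.0436). With an estimated correlation it did not pass (adjusted p = 0.266). By fry, which makes no comparison with other genes, the adjusted p of the p53 list was 7.5e-05. Its means were higher in all 5 exposed mice than in all 5 unexposed mice (exact permutation p = 0.00794, n = 5 per group, the smallest that relabelling 10 mice can give). Phlda3 lost its call without exposed mouse 2 or 4 or unexposed mouse 2 (adjusted p 0.0239 to 0.0574, highest without exposed mouse 2). Tnfrsf10b lost its call in 9 of the 10 fits, all but those without exposed mouse 1 (adjusted p 0.0246 to 0.0938, highest without unexposed mouse 4).

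Interstitial matrix genes were higher in exposed mice, with collagen, tenascin and thrombospondin transcripts in front. Of 24 fibrillar collagen and interstitial matrix genes, 11 rose, 1 fell and 12 did not pass (18 and 1 adjusted over the list alone), with a mean of 0.60 (adjusted p = 2.70e-08, adjusted p = 0.317 with an estimated correlation). Tnc, which encodes the provisional matrix glycoprotein tenascin C, rose 5.50-fold (log2 change 2.46, SE 0.33, adjusted p = 0.000783) and Thbs1 2.79-fold. Col3a1 rose 2.05-fold, from 9.98 ± 0.22 to 11.01 ± 0.36 (SD, n = 5 each), and Col1a1 1.83-fold, from 8.87 ± 0.12 to 9.74 ± 0.50 (SD, n = 5 each); Fn1 changed by 0.60 (SE 0.26, adjusted p = 0.175). The small proteoglycan Fmod fell (-1.81). Of 24 matrix proteases and inhibitors, 10 rose and 2 fell (14 and 2 adjusted over the list alone), with a mean of 0.67 (adjusted p = 2.74e-07, adjusted p = 0.266 with an estimated correlation). The inhibitor Timp1 (3.67) and the protease Mmp19 (2.28) led the rises, and the inhibitors Timp4 (-0.88) and Timp3 (-0.76) fell. Of 21 genes of collagen processing and crosslinking, 5 rose and 3 fell (6 and 3 adjusted over the list alone), with a mean of 0.27 (adjusted p = 0.00607, adjusted p = 0.515 with an estimated correlation). The collagen prolyl hydroxylase subunits went both ways, P4ha3 rising (1.78) and P4ha1 (-0.61) and P4ha2 (-0.53) falling. The crosslinking oxidases Lox (1.00) and Loxl1 (0.71), the procollagen protease Bmp1 (0.57) and its enhancer Pcolce (0.57) rose, and Pcolce2 fell (-0.90). Of 21 basement membrane genes, 6 rose and 3 fell (8 and 3 adjusted over the list alone), with a mean of 0.30 (adjusted p = 0.0265, adjusted p = 0.445 with an estimated correlation). Col4a1 (1.50) and Col4a2 (1.36), the widespread type IV collagen chains, rose, while Lama5 (-0.47), Col4a6 (-0.44) and Col4a4 (-0.38) fell. Of 9 hyaluronan genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone), with a mean of 0.57 (adjusted p = 0.00607, adjusted p = 0.174 with an estimated correlation). They were the receptor Hmmr (2.25), also counted under mitosis, the synthase Has1 (1.24), Tnfaip6 (0.94) and the scavenger receptor Stab1 (0.83). Loxl1, Bmp1, Pcolce, P4ha2, Col4a4, Tnfaip6 and Stab1 were named after their values were seen. Col1a1 lost its call without exposed mouse 4 (adjusted p 0.00486 to 0.0501), and Fmod without exposed mouse 4 or unexposed mouse 2 or 5 (adjusted p 0.00120 to 0.0545, highest without exposed mouse 4). Timp4 lost its call in 6 of the 10 fits, all but those without exposed mouse 1, 3 or 5 or unexposed mouse 5 (adjusted p 0.0249 to 0.0874, highest without unexposed mouse 4). Lox lost its call without unexposed mouse 1 or 4 (adjusted p 0.00854 to 0.0617, highest without unexposed mouse 1). Bmp1 lost its call in 6 of the 10 fits, all but those without exposed mouse 1 or 5 or unexposed mouse 2 or 3 (adjusted p 0.0178 to 0.0810, highest without unexposed mouse 4). P4ha1 lost its call in 7 of the 10 fits, all but those without exposed mouse 3, 4 or 5 (adjusted p 0.0420 to 0.112, highest without unexposed mouse 3). P4ha2 lost its call in 9 of the 10 fits, all but those without exposed mouse 3 (adjusted p 0.00973 to 0.107, highest without exposed mouse 4). Col4a4 lost its call in 8 of the 10 fits, all but those without exposed mouse 3 or unexposed mouse 1 (adjusted p 0.0141 to 0.0740, highest without unexposed mouse 4). Col4a6 lost its call in 8 of the 10 fits, all but those without exposed mouse 1 or unexposed mouse 1 (adjusted p 0.0210 to 0.102, highest without exposed mouse 4). Stab1 lost its call without exposed mouse 5 or unexposed mouse 2, 4 or 5 (adjusted p 0.00952 to 0.0594, highest without unexposed mouse 4). The mean change of the collagen processing list became 0.17 without exposed mouse 3. That list also missed the threshold without exposed mice 1 and 3 (adjusted p = 0.0504, with 0.00128 to 0.515 over its alternatives), a choice made after the data were seen.

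Among mesenchymal cell types, genes of activated fibroblasts were higher, smooth muscle genes were not shifted as a list, and cartilage genes were lower. Of 22 fibroblast activation genes, 7 rose and 1 fell (9 and 2 adjusted over the list alone), with a mean of 0.55 (adjusted p = 0.000295, adjusted p = 0.445 with an estimated correlation). Tnc (2.46) and Cthrc1 (2.26), a secreted marker of matrix-producing fibroblasts, rose most, and the transcription factor Runx1 fell (-0.46). Acta2, the smooth muscle actin that myofibroblasts also make, changed by 0.09 (95% interval -0.31 to 0.48, adjusted p = 0.825), and this value turned to -0.027 without unexposed mouse 2. Of 15 smooth muscle genes 14 did not pass and Itga8 fell (-0.71), 1 of 15 also when adjusted over the list alone (mean -0.043, adjusted p = 0.675). Of 18 genes of resting and adventitial fibroblasts, C7 (1.39), Mfap5 (0.75), Tcf21 (0.71) and Pdgfra (0.68) rose and Inmt (-2.05), Ces1d (-1.85) and Gsn (-0.71) fell (7 and 3 adjusted over the list alone), and the list did not pass (mean 0.029, adjusted p = 0.287). Of 10 pericyte genes, the potassium channel subunit Kcnj8 (1.13) and Higd1b (0.52) rose and 0 fell (4 and 0 adjusted over the list alone), with a mean of 0.29 (adjusted p = 0.0205, adjusted p = 0.445 with an estimated correlation). Of 22 cartilage genes, 4 fell and 0 rose (9 and 0 adjusted over the list alone), with a mean of -0.84 (adjusted p = 6.17e-06, adjusted p = 0.445 with an estimated correlation). They were Cnmd (-2.41), a cartilage-specific growth regulator, the matrilins Matn1 (-1.56) and Matn3 (-1.19), and Chad (-1.05). Cartilage means ranged from 6.46 to 8.48 in exposed and from 7.81 to 8.72 in unexposed mice. With the pan-epithelial covariate, chosen after the data were seen, 9 of the 22 cartilage genes fell. Tcf21, Pdgfra, Gsn, Matn3 and Chad were named after their values were seen. The pericyte list lost its call without exposed mouse 3 (adjusted p = 0.107, with 0.00327 to 0.107 over the 10 fits). Itga8 lost its call without exposed mouse 2 or 4 or unexposed mouse 3 or 5 (adjusted p 0.0144 to 0.0664, highest without exposed mouse 4). Pdgfra lost its call without unexposed mouse 1 or 5 (adjusted p 0.0151 to 0.0540, highest without unexposed mouse 1). Higd1b lost its call in 8 of the 10 fits, all but those without exposed mouse 1 or unexposed mouse 3 (adjusted p 0.00367 to 0.0720, highest without exposed mouse 4). Matn3 lost its call in 6 of the 10 fits, all but those without exposed mouse 1 or 3 or unexposed mouse 1 or 4 (adjusted p 0.0101 to 0.0652, highest without exposed mouse 2). Chad lost its call in 8 of the 10 fits, all but those without exposed mouse 1 or 3 (adjusted p 0.0154 to 0.107, highest without exposed mouse 4).

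Among signalling pathways, the BMP list was lower and the growth factor list higher, and the TGF-beta, Wnt and hedgehog lists did not pass. Of 17 BMP pathway genes, 2 rose and 5 fell (3 and 8 adjusted over the list alone), with a mean of -0.26 (adjusted p = 0.0181, adjusted p = 0.397 with an estimated correlation). The antagonists Fst (1.75) and Chrd (0.36) rose, and the receptor Bmpr1b (-1.61), the ligands Bmp5 (-0.80) and Bmp4 (-0.71) and the target genes Id4 (-0.74) and Id2 (-0.53) fell. Exposed mouse 5 held the lowest BMP (6.25) and cartilage (6.46) means of all mice. Exposed mouse 3 had a cartilage mean of 8.48, within the unexposed range, yet a BMP mean of 6.58, below the unexposed range. Whether the BMP fall follows the cartilage in the captures was not tested. Of 20 growth factors and receptors, 7 rose and 2 fell (9 and 3 adjusted over the list alone), with a mean of 0.33 (adjusted p = 0.0352, adjusted p = 0.445 with an estimated correlation). Ereg, a ligand of the EGF receptor (2.33), and Hgf (1.44) rose most, and Fgf1 (-0.91) and Vegfa (-0.76) fell. Of 22 TGF-beta pathway genes, the activin subunit Inhba (1.34) and the latency protein Ltbp1 (0.63) rose and 20 did not pass (5 higher and 1 lower adjusted over the list alone), and the list did not pass (mean 0.15, adjusted p = 0.154). Tgfb1 changed by 0.51 (SE 0.16, adjusted p = 0.0615). With the pan-epithelial covariate, chosen after the data were seen, 7 genes of the TGF-beta list rose, 1 fell and Tgfb1 passed (adjusted p = 0.00953, with 0.00953 to 0.139 over its alternatives). Tgfb1 also passed without exposed mouse 1 (adjusted p = 0.0447), without dim genes (adjusted p = 0.0395), with array weights (adjusted p = 0.0448) and with trend and robust settings (adjusted p = 0.0418). Without exposed mice 1 and 3, also chosen after the data were seen, 3 genes of that list rose and 2 fell (mean 0.054). With 1 mouse left out, the TGF-beta list mean ranged from 0.058 to 0.203, and the list did not pass (camera adjusted p 0.0504 to 0.428). Of 30 Wnt pathway genes, the secreted inhibitor Sfrp1 rose (0.79), the inhibitors Sfrp2 (-1.38) and Wif1 (-1.20) and the receptor Lgr6 (-1.10) fell, the same numbers as adjusted over the list alone, and the list did not pass (mean -0.14, adjusted p = 0.107). None of 9 hedgehog pathway genes passed by limma, over all genes or adjusted over the list alone (mean -0.073, adjusted p = 0.508). Id4, Bmp4, Id2 and Lgr6 were named after their values were seen. The growth factor list lost its call without exposed mouse 3 (adjusted p = 0.0742, with 0.0175 to 0.0742 over the 10 fits). Chrd lost its call without exposed mouse 4 or 5 or unexposed mouse 1 or 4 (adjusted p 0.0203 to 0.0689, highest without unexposed mouse 1). Id2 lost its call in 6 of the 10 fits, all but those without exposed mouse 1, 3 or 4 or unexposed mouse 4 (adjusted p 0.0220 to 0.0736, highest without unexposed mouse 1).

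Transcripts of the monocyte and macrophage lineage were higher in exposed mice, and so were chemokines as a list. With an estimated correlation neither list kept its call (adjusted p = 0.210 and 0.288). Of 26 monocyte and macrophage genes, 19 rose and 0 fell (21 and 0 adjusted over the list alone), with a mean of 1.00, or 1.99-fold (adjusted p = 1.11e-13, adjusted p = 0.210 with an estimated correlation). The chitinase-like gene Chil3 rose 9.53-fold (log2 change 3.25, SE 0.39, adjusted p = 0.000377) and Ms4a7 4.29-fold, whereas Cd14, Lyz2 and Ccr2 changed by -0.28, -0.34 and -0.36 (adjusted p = 0.297, 0.213 and 0.407). Ptprc, carried by all leukocytes, changed by 0.22 (SE 0.23, adjusted p = 0.628). Of 20 chemokines, 8 rose and 2 fell, the same numbers as adjusted over the list alone, with a mean of 0.96 (adjusted p = 0.000295, adjusted p = 0.288 with an estimated correlation). Ccl8 (3.98) and Ccl12 (2.92) led the rises, and Ccl20 (-1.80) and Cx3cl1 (-0.51) fell. Of 18 inflammatory cytokines and mediators, 7 rose and 0 fell, also when adjusted over the list alone, with a mean of 0.51 (adjusted p = 0.000295, adjusted p = 0.266 with an estimated correlation). Il6 rose 5.43-fold, from a low mean log2 value of 2.86 in unexposed mice, and the prostaglandin synthase Ptgs2 2.65-fold. Of 13 complement genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with a mean of 0.57 (adjusted p = 0.000777, adjusted p = 0.286 with an estimated correlation). The anaphylatoxin receptors C3ar1 (1.79) and C5ar1 (1.43) rose most, and the regulator Cd55 (-0.65) and Cfb (-0.53) fell. Of 16 interferon response genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone), with a mean of 0.41 (adjusted p = 0.000263, adjusted p = 0.308 with an estimated correlation). Bst2 (0.93) and Gbp3 (0.83) rose most and Oas2 fell (-0.48). Cd14, Lyz2 and Ccr2 were named after their values were seen. Cx3cl1 lost its call without exposed mouse 3 or 4 or unexposed mouse 1, 2 or 4 (adjusted p 0.0253 to 0.0923, highest without unexposed mouse 1). Cfb lost its call in 9 of the 10 fits, all but those without unexposed mouse 5 (adjusted p 0.0163 to 0.111, highest without unexposed mouse 4). Gbp3 lost its call without exposed mouse 2 or 4 or unexposed mouse 1 or 5 (adjusted p 0.00281 to 0.0619, highest without unexposed mouse 1). Oas2 also missed the threshold without exposed mice 1 and 3 (adjusted p = 0.0649, with 0.00644 to 0.0649 over its alternatives), a choice made after the data were seen.

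Of 17 neutrophil genes, 4 rose and 1 fell (6 and 2 adjusted over the list alone), with a mean of 0.42 (adjusted p = 0.0190, adjusted p = 0.286 with an estimated correlation). The calprotectin subunits S100a8 (2.43) and S100a9 (1.59), the collagenase Mmp8 (1.12) and the decoy receptor Il1r2 (0.87) rose, and Cd177 fell (-1.51). Of 12 dendritic cell and class II genes, 4 fell and 0 rose (4 and 1 adjusted over the list alone), with a mean of -0.32 (adjusted p = 0.00607, adjusted p = 0.317 with an estimated correlation). They were the class II chains H2-Aa (-1.24) and H2-Ab1 (-1.11), the chemokine receptor Xcr1 (-0.81) and Cd209a (-0.71). Of 15 type 2 response genes, Chil3 (3.25), the alarmins Il33 (1.78) and Tslp (0.66), the receptor chain Il4ra (1.14) and the enzyme Arg1 (0.98) rose and Retnla fell (-3.45), 5 and 4 adjusted over the list alone, and the list did not pass (mean 0.18, adjusted p = 0.313). Of 19 T and NK cell genes, Cd3g (-2.08) and Ncr1 (-0.51) fell, also when adjusted over the list alone, and the list did not pass (mean -0.20, adjusted p = 0.347). It did without exposed mouse 4 (mean -0.37, adjusted p = 0.00319, with 0.00319 to 0.920 over its alternatives). Of 12 B and plasma cell genes, Mzb1 (-0.83) and Blk (-0.59) fell, also when adjusted over the list alone, and the list did not pass (mean -0.11, adjusted p = 0.575). By limma no gene passed among 12 mast cell genes (adjusted p = 0.844) and 5 eosinophil genes (adjusted p = 0.726), also when adjusted over the list alone. The mean and median of these lists differed in sign, -0.045 and 0.012 for mast cells and -0.020 and 0.031 for eosinophils. Mmp8, Il1r2, Il4ra, Arg1, Tslp, Xcr1 and Cd209a were named after their values were seen. S100a9 lost its call without exposed mouse 2 or 4 or unexposed mouse 1 or 5 (adjusted p 0.00454 to 0.0624, highest without unexposed mouse 1). Cd209a lost its call without unexposed mouse 2, 3 or 4 (adjusted p 0.00946 to 0.0594, highest without unexposed mouse 3). Tslp lost its call in 7 of the 10 fits, all but those without exposed mouse 3 or unexposed mouse 1 or 3 (adjusted p 0.0149 to 0.0933, highest without unexposed mouse 2). Ncr1 lost its call in 7 of the 10 fits, all but those without exposed mouse 1 or 4 or unexposed mouse 2 (adjusted p 0.0147 to 0.0810, highest without unexposed mouse 3). Mzb1 lost its call in 6 of the 10 fits, all but those without exposed mouse 1, 2, 3 or 4 (adjusted p 0.0130 to 0.0750, highest without unexposed mouse 4). Blk lost its call without unexposed mouse 1 (adjusted p 0.00389 to 0.0501). Cd209a had 2 probe sets and changed by -0.11 with its brightest probe set alone (adjusted p = 0.755, with 0.00946 to 0.755 over its alternatives). Without exposed mice 1 and 3, a choice made after the data were seen, the class II list (adjusted p = 0.0617, with 0.000712 to 0.317 over its alternatives) and Cd3g (adjusted p = 0.0527, with 0.000324 to 0.0527) missed the threshold. The class II list also missed it without dim genes (adjusted p = 0.0675).

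The endothelial and lymphatic lists were called against other genes, but not by exact permutation of the mouse means (adjusted p = 0.105 and 0.0547). Genes of nerve, fat, skeletal muscle and thyroid, which lie beside or around the trachea, were not shifted as lists. Of 22 endothelial genes, Eng (0.86) and Tek (0.46) rose and 0 fell (4 and 0 adjusted over the list alone), with a mean of 0.30 (adjusted p = 0.0016, adjusted p = 0.452 with an estimated correlation). Of 6 lymphatic endothelial genes, Lyve1 (0.57) and Pdpn (0.47) rose and 0 fell, also when adjusted over the list alone, with a mean of 0.30 (adjusted p = 0.0262, adjusted p = 0.397 with an estimated correlation). Of 15 Schwann cell and nerve genes, Egr2 alone rose (0.90), also when adjusted over the list alone; the mean was -0.010 while the test leaned up (adjusted p = 0.837). None of 12 adipocyte genes passed by limma, over all genes or adjusted over the list alone (mean -0.040, adjusted p = 0.615), and that mean became 0.37 without exposed mouse 2. Of 19 skeletal muscle genes, Tnnt3 (-1.07), Casq1 (-0.66) and Myh7 (-0.50) fell, also when adjusted over the list alone; the mean was -0.058, the median 0.032 and the adjusted p 0.508. Of 6 thyroid genes, Iyd fell (-0.64), also when adjusted over the list alone (mean -0.13, adjusted p = 0.490). The erythroid list had fewer than 5 measured genes and was not tested. Myh7 was named after its values were seen. The lymphatic list lost its call without exposed mouse 2 (adjusted p = 0.0666), unexposed mouse 2 (adjusted p = 0.0575) or unexposed mouse 5 (adjusted p = 0.0611), with 0.00874 to 0.0666 over the 10 fits. Eng lost its call without exposed mouse 4 or unexposed mouse 1, 2, 3 or 5 (adjusted p 0.0175 to 0.0778, highest without unexposed mouse 2). Tek lost its call in 8 of the 10 fits, all but those without exposed mouse 1 or unexposed mouse 3 (adjusted p 0.0143 to 0.114, highest without unexposed mouse 1). Pdpn lost its call in 7 of the 10 fits, all but those without exposed mouse 1 or 5 or unexposed mouse 3 (adjusted p 0.0158 to 0.0892, highest without unexposed mouse 1). Tnnt3 lost its call without exposed mouse 2 or unexposed mouse 3 (adjusted p 0.0232 to 0.0623, highest without exposed mouse 2). Myh7 lost its call in 7 of the 10 fits, all but those without exposed mouse 1 or unexposed mouse 3 or 4 (adjusted p 0.0276 to 0.105, highest without unexposed mouse 1). Iyd lost its call in 9 of the 10 fits, all but those without exposed mouse 1 (adjusted p 0.00280 to 0.106, highest without exposed mouse 5).

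Most circadian clock genes were lower in exposed mice. Of 16 clock genes, 10 fell and 1 rose (11 and 3 adjusted over the list alone), and the list mean changed by -0.50 (adjusted p = 6.17e-06 against other genes). Among the 30 lists called this was the call that held with an estimated correlation (adjusted p = 0.0399). The list mean was 7.50 ± 0.056 in unexposed mice and 7.003 ± 0.020 in exposed mice (SD, n = 5 each). Single genes spread more than this mean, Dbp with SDs of 0.24 and 0.23. Per3 fell (log2 change -1.39, SE 0.11, adjusted p = 3.97e-05) and so did the transcription factor Dbp (-1.07) and Cry1 (-0.64), while the repressor Nfil3 rose (0.77). Arntl, also known as Bmal1 (0.44), Npas2 (0.16) and Clock (0.23), which form the activating arm of the clock, did not pass (adjusted p = 0.107, 0.377 and 0.119). Arntl passed without unexposed mouse 2 (adjusted p = 0.0317, with 0.0317 to 0.261 over its alternatives), and Clock passed when the dimmer genes were left out (adjusted p = 0.0451) or with trend and robust settings (adjusted p = 0.0476). Cry1, Arntl, Npas2 and Clock were named after their values were seen.

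Stress and metabolic lists went different ways. Of 15 genes of the NRF2 oxidative stress response, 7 fell and 0 rose, also when adjusted over the list alone, with a mean of -0.46 (adjusted p = 5.88e-05, adjusted p = 0.266 with an estimated correlation). Gclc, which makes the precursor of glutathione, fell (-1.35), as did the glutathione transferase Gstm1 (-1.17). Exposed mouse 3 held the lowest NRF2 mean (6.95) and the lowest luminal and secretory mean (6.26) of all mice. Exposed mouse 1, with a luminal and secretory mean of 9.23, still had an NRF2 mean of 7.34, against 7.60 to 7.87 in unexposed mice. Whether the NRF2 fall follows the loss of airway secretory transcripts was not tested. Of 12 glucocorticoid response genes, 5 rose and 0 fell (5 and 1 adjusted over the list alone), with a mean of 0.63 (adjusted p = 0.000368, adjusted p = 0.288 with an estimated correlation). They were the metallothioneins Mt2 (2.27) and Mt1 (1.45), which metals and inflammation also induce, Fkbp5 (1.39), Zbtb16 (1.07) and Cdkn1a (1.03). All 22 ribosomal protein genes had changes above 0, of which Rplp0 (0.41) passed (4 adjusted over the list alone), with a mean of 0.21 (adjusted p = 8.98e-05, adjusted p = 0.266 with an estimated correlation). Of 19 hypoxia and glycolysis genes, 6 rose and 2 fell (8 and 2 adjusted over the list alone), with a mean of 0.11 (adjusted p = 0.0375, adjusted p = 0.266 with an estimated correlation). The glycolytic enzyme Pkm (0.60) and Ndrg1 (0.49) rose most, and Vegfa (-0.76) and Pdk1 (-0.57) fell. None of 20 oxidative phosphorylation genes passed by limma, over all genes or adjusted over the list alone (mean 0.079, adjusted p = 0.154), though the list passed without exposed mouse 3 (adjusted p = 0.0241, with 0.0241 to 0.705 over its alternatives). Of 19 unfolded protein response genes, Herpud1 (-0.73) and Dnajb9 (-0.42) fell, also when adjusted over the list alone (mean -0.070, median 0.001, adjusted p = 0.490). Of 15 cholesterol synthesis genes, Fdps rose (0.48) and Insig1 fell (-0.98), with 2 and 1 adjusted over the list alone (mean 0.053, adjusted p = 0.313). Of 16 immediate early genes, Egr2 rose (0.90), with 1 higher and 1 lower adjusted over the list alone (mean -0.12, adjusted p = 0.313). Fkbp5 and Zbtb16 were named after their values were seen. The hypoxia list lost its call without exposed mouse 1 (adjusted p = 0.0646), 3 (adjusted p = 0.0543) or 5 (adjusted p = 0.0746), with 0.0224 to 0.0746 over the 10 fits. Zbtb16 lost its call in 6 of the 10 fits, all but those without exposed mouse 1 or 2 or unexposed mouse 3 or 5 (adjusted p 0.00928 to 0.0696, highest without unexposed mouse 1). Rplp0 lost its call without unexposed mouse 1 (adjusted p 0.00840 to 0.0509), and Dnajb9 without exposed mouse 2 or unexposed mouse 1, 4 or 5 (adjusted p 0.0212 to 0.0672, highest without unexposed mouse 1). Fdps lost its call in 9 of the 10 fits, all but those without exposed mouse 3 (adjusted p 0.00861 to 0.0972, highest without exposed mouse 2).

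**Figure D3:**
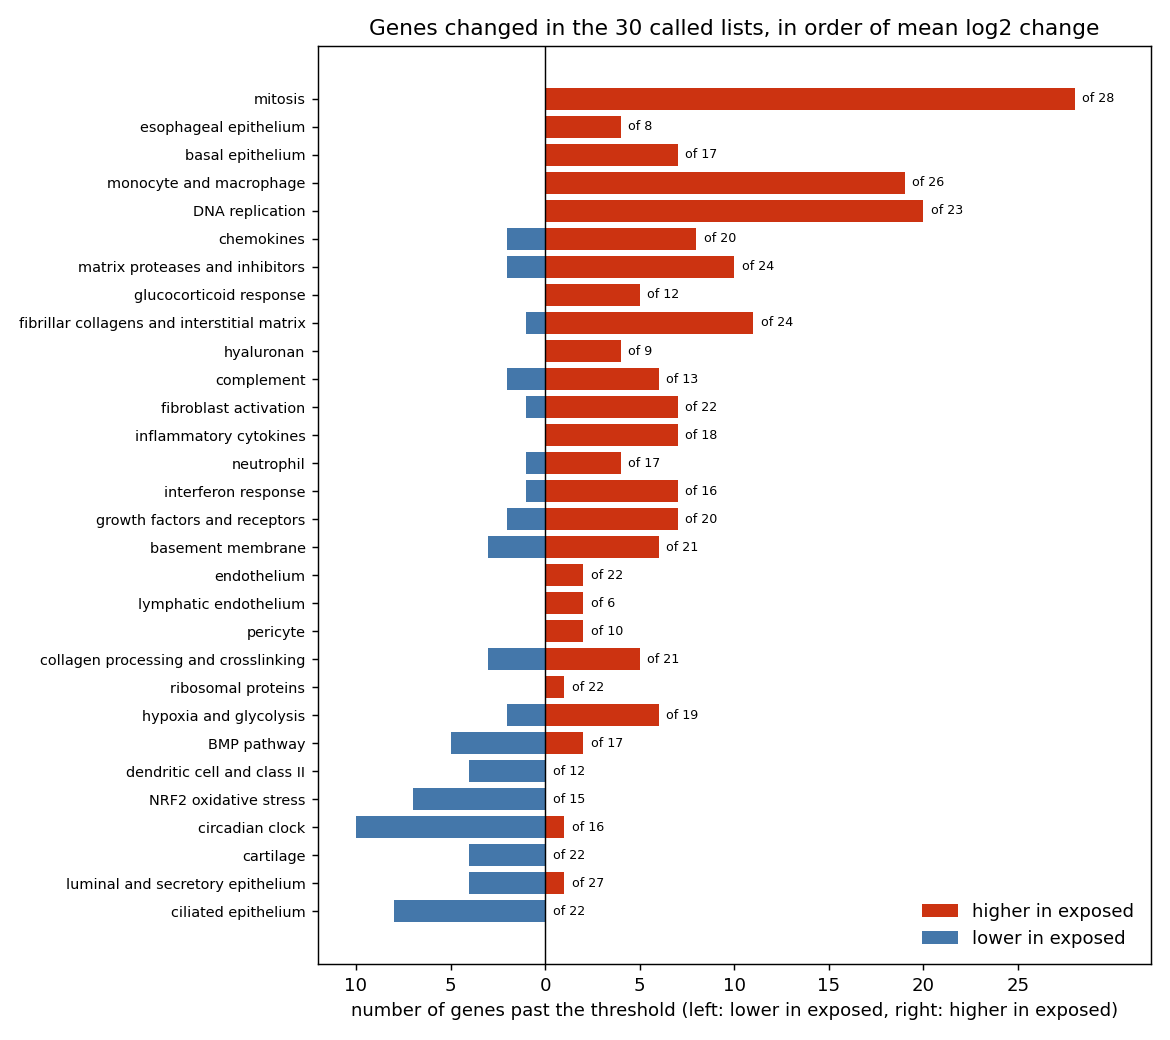
Number of genes past the threshold in each of the 30 gene lists that were called, with genes higher in exposed mice in red to the right, genes lower in blue to the left and the number measured beside each bar, in order of the list's mean log2 change. Mitosis, with all 28 genes higher, stands at the top and ciliated epithelium, with 8 of 22 lower, at the bottom.

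Of 50 lists tested, 30 stood apart from other genes with a preset correlation between genes of 0.01, 23 higher and 7 lower, but 1 did with an estimated correlation, and 26 shifted by exact permutation of the mice (17 without unexposed mouse 1). Called lists that did not shift by permutation were those of ciliated cells, cartilage, endothelium, lymphatic endothelium, collagen processing (adjusted p = 0.0661), pericytes (adjusted p = 0.0547) and hypoxia (adjusted p = 0.0868). The p53 (adjusted p = 0.022), Wnt (adjusted p = 0.0458) and submucosal gland lists shifted by permutation without being called. Other splits of the 10 mice called from 0 to 31 lists with the preset correlation.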

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

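The tests on the epithelial, matrix and clock patterns were chosen after the list values had been seen, whereas the counts over other splits of the mice were set beforehand. Of 100 splits of the 10 mice into groups of 5, drawn at random with the real one included, only the real one reached either count. The real split gave 1298 genes higher and 1102 lower, and another split gave at most 3 in either direction. Such counts were thus rare among the splits drawn. Mixed splits put the difference between the groups into the spread within them, which lowers their counts. Nor can the splits separate exposure from anything else that differed between the groups. The real split called 30 lists and 3 of the 100 splits, the real one included, called as many, with 31 as the highest other. A count as high was thus uncommon among the splits, and its share lay under the limit set beforehand. Chance is nonetheless not excluded for the list count. Another split called more lists than the real one, other splits called from 0 to 31, and the real split called 1 with an estimated correlation.

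Of 17 basal genes 7 rose and of 22 ciliated genes 8 fell, and neither list kept its call with an estimated correlation (adjusted p = 0.312 and 0.397). A smaller share of epithelium in the exposed captures would lower both lists. The basal list instead rose by 1.15 on average, which argues against such a loss as the whole cause. The basal change exceeded the ciliated change by 2.725 log2 units (exact permutation p = 0.00794, n = 5 per group). That difference restates the pattern, so its p adds no support. Esophageal epithelium caught in exposed sections cannot be told apart from a change within the trachea, because the median change of the 7 esophageal markers other than Sprr1a was 0.789, with Krt13 at 2.96 but Rptn at -0.05 and Crnn at 0.09. Airway basal cells under repair may also express several of these genes, and a response of the epithelium to chlorine stays open as an untested hypothesis. Exposed mouse 3 stood below the other exposed mice in the basal list (7.31) and the esophageal list (5.16), and its pan-epithelial mean was 8.27, with Krt13 (5.74), Krt4 (4.82) and Krtdap (4.83) near or below unexposed values beside Sprr1a (10.23), Krt14 (10.98) and Psca (9.37) above them.

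Of 24 matrix genes 11 rose and 1 fell, and the list lost its call with an estimated correlation (adjusted p = 0.317). If a smaller share of epithelium had raised all mesenchymal genes alike, the matrix list (0.60) would have moved with 3 other lists. Those of resting fibroblasts, smooth muscle and pericytes changed by 0.029, -0.043 and 0.287, which argues against this as the whole cause. The matrix change exceeded their mean by 0.511 (exact permutation p = 0.0159, n = 5 per group). This contrast was chosen after those changes were seen, so its p is descriptive only. Less cartilage in exposed captures is also argued against as the whole cause, since the matrix change was 0.859 (95% interval 0.481 to 1.238) with the cartilage mean as a covariate. A response of fibroblasts to exposure, in number or in activity, stays open. Exposed mouse 3 held the highest Lox (9.69) and Tgfb1 (8.12) values of its group beside the lowest basal, luminal and pan-epithelial means. It also held the highest smooth muscle (9.64), pericyte (7.96) and endothelial (7.04) means of its group. Less epithelium in its capture therefore cannot be told apart from a stronger response in that mouse.

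Of 16 clock genes, 10 fell and 1 rose. Loss of ciliated cells is argued against as the cause, since the clock list changed by -0.494 (95% interval -0.589 to -0.398) with the ciliated mean as a covariate. Collection at another time of day would move the clock's arms apart, and Arntl, Npas2, Clock and Nfil3, which peak opposite to the rest, changed by 0.402 on average (exact permutation p = 0.00794, n = 5 per group) while the other 12 genes changed by -0.799 (exact permutation p = 0.00794). That is consistent with a difference in collection time, which the labels do not give, although Cry1, whose peak lies later than that of Dbp or Per3, fell as well (-0.64). The clock genes were divided in this way after their changes were seen, so both p values are descriptive only. Nfil3 (0.77) had the largest of the rises, and Arntl, Npas2 and Clock did not pass by themselves. A shift of the clock by exposure itself was not tested and stays open.

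Single values that lay apart from the other 4 mice of their group were found in 35 of 446 groups tested, where chance gives about 1 in 20, or about 22.3. In exposed mouse 3, A2ml1 (4.41), Dsg3 (6.88), Krt13 (5.74), Krt4 (4.82), Krtdap (4.83), Scgb1a1 (6.89) and Tslp (4.92) were lowest. In exposed mouse 4, the T and NK cell list (5.43) and the B and plasma cell list (4.68) were highest and Npas2 (6.41) was lowest. In exposed mouse 2, the adipocyte (6.47), thyroid (4.54) and p53 target (6.80) lists and Zbtb16 (7.22) were lowest and Ccr2 (7.03) was highest. In exposed mouse 1, Cd209a (5.81) and Higd1b (5.46) were lowest, and in exposed mouse 5, Timp3 (9.94) was lowest and Ndrg1 (8.75) highest. Among unexposed mice, the interferon list (6.17), Blk (4.59), Cd55 (6.88), Ces1d (8.49) and Ptprc (6.63) were lowest in mouse 5, Inmt (7.35) was lowest and Dsg3 (4.91) and Krt13 (8.19) highest in mouse 2. Cdkn1a (7.97) was lowest and Bpifb1 (12.02) and Gclc (9.26) highest in unexposed mouse 4, and Fdps (6.31) was lowest in unexposed mouse 3.

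Probe sets outside the gene comparison also differed. When every probe set was tested by itself, 311 of the 16010 that the annotation does not list were called (143 higher and 168 lower in exposed mice), as were 114 of the 1814 with several symbols (79 higher and 35 lower).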

How the results depend on the processing

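The fits without exposed mice 1 and 3 and with the pan-epithelial covariate, and the pan-epithelial mean without each mouse, were chosen after the data were seen; the other settings were fixed beforehand. The counts of 1298 genes higher and 1102 lower stayed within 1.5 times under renormalization, median centring, dim-gene filters, other probe set rules, other eBayes settings and array weights, and without exposed mice 1 and 3 (1413 and 1335) or with the covariate (1507 and 1374). Stricter thresholds gave fewer genes by construction, with 619 and 435 at an adjusted p under 0.01, 411 and 349 at 2-fold or more and 504 and 345 against a 1.2-fold change. Leaving out 1 mouse at a time gave 944 to 1432 genes higher and 723 to 1407 lower. Between 67.7% and 99.5% of called genes kept their calls under the other alternatives that refit each gene, and every called gene tested kept its direction there. The stricter thresholds kept 43.9%, 31.7% and 35.4%, and no such share was counted for single probe sets. Over named genes and alternatives, 3100 of 3391 comparisons kept direction and side of the threshold, 275 lost the call, 15 gained one and 1 reversed, and of 157 named genes called 115 kept the call whichever mouse was left out. Calls ended for Chad, Myh7, P4ha1 and Tek with quantile normalization (adjusted p = 0.0504 to 0.0708) and for Cfb, Iyd, Myh7, P4ha1 and P4ha2 with median centring (adjusted p = 0.0523 to 0.0588). They ended for Chad, Krt13, Tmem212 and Tnfrsf10b with trend and robust settings (adjusted p = 0.0529 to 0.095), for Cfb and Myh7 with array weights (adjusted p = 0.0506 and 0.06), and for 12 genes without exposed mice 1 and 3. The cause was not tested.

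Of the 30 lists called, 22 of the 29 still tested kept the call with dim genes left out, 23 of 30 by fry, 28 without shared members, 27 without exposed mice 1 and 3, and 27 to 30 with 1 mouse left out. With an estimated correlation 1 list was called, and the cause was not tested. Without dim genes the calls of the pericyte (adjusted p = 0.056), BMP (0.0552), growth factor (0.056), neutrophil (0.295), class II (0.0675), lymphatic (0.0863) and hypoxia (0.107) lists ended. Those of the neutrophil (0.0716) and lymphatic (0.0844) lists ended without shared members, and that of the hypoxia list with quantile normalization (0.0532) and without exposed mice 1 and 3 (0.0912). By fry the collagen processing (0.0881), cartilage (0.119), pericyte (0.0881), luminal (0.2), ciliated (0.0581), endothelial (0.128) and lymphatic (0.0529) lists were not called, and the Wnt (0.0347) and p53 (7.5e-05) lists were. By exact permutation per mouse 26 lists shifted, and 17 to 27 with 1 mouse left out, with the smallest count without unexposed mouse 1. No called list reversed. Reversals were found in uncalled results, and their causes were not tested. The nerve list became 0.007 with median centring and 0.014 without dim genes, the resting fibroblast list -0.088 and the type 2 list -0.119 without shared members, and the eosinophil list 0.004 without exposed mice 1 and 3. With 1 mouse left out, Acta2 ranged from -0.027 to 0.185, the resting fibroblast list from -0.013 to 0.082, smooth muscle from -0.144 to 0.062, mast cells from -0.138 to 0.028, eosinophils from -0.08 to 0.017, nerve from -0.048 to 0.017, adipocytes from -0.187 to 0.366, skeletal muscle from -0.103 to 0.001 and the pan-epithelial mean from -0.104 to 0.143.

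Nothing in the labels pairs mice of the same number, and the values cannot settle whether such mice were handled together. Deviations of same-numbered mice correlated across genes at 0.125, -0.049, 0.115, -0.033 and -0.03, and only number 1 correlated best with its own number. With the mouse number as a replicate block, 1026 genes were higher, 854 lower and 28 lists called, with the growth factor and hypoxia lists lost (adjusted p = 0.0566 for both). Of the named genes 24 lost their calls under the block, among them Il1r2 (adjusted p = 0.0559), Lyve1 (0.0668), Matn1 (0.0538) and Runx1 (0.0521), which kept them whichever mouse was left out. The exact permutation test was not run under the block, because its 32 relabellings cannot give a p under 0.0625. Array values carry no signal over background here, so what low signal limits was not measured.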

Other observations

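The families in this part were picked by gene name after the results had been seen, so all tests in this part were chosen only after the result was seen. Of 16 glutathione S-transferases, 10 fell and 0 rose, with a mean log2 change of -0.82 (adjusted p = 1.77e-07 by camera over 16 families, adjusted p = 0.0583 with an estimated correlation), and of 6 flavin monooxygenases, 4 fell (Fmo6 -3.08, Fmo2 -1.65, Fmo1 -0.69 and Fmo5 -0.54 on the log2 scale) and 0 rose, with a mean of -0.98 (adjusted p = 0.000614, adjusted p = 0.0724 with an estimated correlation). Of 62 cytochromes P450 of families 2 and 4, 6 fell and 0 rose, and the family did not pass (mean -0.30, adjusted p = 0.0563). Of 4 surfactant proteins measured, 3 fell and 0 rose, with a mean of -2.60 (adjusted p = 1.50e-05, adjusted p = 0.0583 with an estimated correlation); Sftpa1 changed by -4.94, Sftpb by -2.73 and Sftpd by -2.21. Of 43 axonemal dyneins and cilia-associated proteins, 15 fell and 0 rose, with a mean of -1.19 (adjusted p = 4.95e-12, adjusted p = 0.200 with an estimated correlation), beside the ciliated list of the report, whose members they share in part. In the same mice the ciliated list changed by -1.57 and the luminal and secretory list by -1.07, and the ciliated mean ranged from 4.85 to 7.51 among exposed mice.

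Other families were higher. Of 7 interferon-inducible p200 genes, several of which encode sensors of nucleic acid, Ifi204 (2.63), Ifi202b (2.41), Ifi205 (1.78), Ifi207 (1.38) and Ifi203-ps (0.79) rose and 0 fell, with a mean of 1.42 (adjusted p = 1.79e-07, adjusted p = 0.0583 with an estimated correlation), and of 9 Schlafen genes, Slfn1 (1.87), Slfn8 (1.51), Slfn5 (1.01), Slfn2 (0.97) and Slfn4 (0.97) rose and 0 fell, with a mean of 0.82 (adjusted p = 1.37e-05, adjusted p = 0.0583 with an estimated correlation). Of 20 membrane-spanning 4A genes, several of them macrophage genes, 8 rose and 0 fell, with a mean of 0.74 (adjusted p = 1.61e-05, adjusted p = 0.0583 with an estimated correlation). Of 11 genes of C-type lectin family 4, 6 rose and Clec4b1 fell (adjusted p = 0.0126, adjusted p = 0.200 with an estimated correlation), and of 16 S100 proteins, 7 rose and S100a1 fell (adjusted p = 1.98e-05, adjusted p = 0.0583 with an estimated correlation). Of 12 small proline-rich proteins, Sprr1a (6.53), Sprr3 (2.50), Sprr1b (1.48), Sprr2f (1.43) and Sprr2b (0.96) rose and 0 fell, with a mean of 1.28 (adjusted p = 3.68e-05, adjusted p = 0.0583 with an estimated correlation), and of 20 centromere proteins, 14 rose and 0 fell, with a mean of 0.89 (adjusted p = 6.71e-13, adjusted p = 0.0583 with an estimated correlation). The 38 kinesins went both ways, with 11 higher, among them the mitotic motors Kif11 (1.93) and Kif23 (2.16), and Kif21a (-1.34), Kif9 (-1.19), Kif27 (-1.18), Kif19a (-0.62) and Kif13b (-0.35) lower (adjusted p = 0.463 for the family). Of 25 clade B serpins, Serpinb2 (4.75), Serpinb5 (2.45) and Serpinb3d (0.45) rose and Serpinb9c fell (-0.45; adjusted p = 0.137). Receptors not usually made in the airway wall served as a comparison, and of 1105 olfactory receptors 10 passed, 5 in each direction (adjusted p = 0.995), while of 289 vomeronasal receptors Vmn1r172 (0.70) and Vmn1r39 (0.53) rose (adjusted p = 0.726).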
